A study of Mus musculus with 2 samples.

How the data were processed

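Total RNA of dissected ureters of mouse embryos (NMRI strain, stage E18.5) was measured on 2 Agilent 2-colour arrays, each of which held RNA labelled cDKO and control RNA. Per the labels, cDKO embryos carried 1 Cre allele of Tbx18 and were homozygous for floxed Tbx2 and for floxed Tbx3, and controls had at least 1 floxed allele of each and no Cre allele. Replicate 1 held RNA of males with the cDKO RNA in AlexaFluor647 (red), and replicate 2 held RNA of females with the dyes exchanged. Sex, dye orientation and replicate number therefore run together. Both arrays lay on 1 slide with 1 scan, so slide and scan could not be set as a block. The labels do not say how many embryos gave each RNA, so p-values of single genes speak only to variation between these 2 arrays. They rest mostly on a variance pooled over probes (prior of 13.9 degrees of freedom against 1), less on each gene's own SD.

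Per the file headers, images were quantified with Agilent Feature Extraction 10.7.3.1, which wrote a mean spot intensity and a median local background intensity for each channel. The deposited processed signal intensity was background-subtracted and dye-normalized by the same program, and its deposited log10 ratio was red over green. The deposited 0 or 1 flags mark spots as saturated, uniform or well above background. The authors' deposited value table is a score whose scale is not stated in the labels. Set against the scanner values, it equalled the signed fold change of labelled cDKO over control processed signals after a floor of 26.9 on replicate 1 and 20.4 on replicate 2, within 0.001 log2 for 100% of 44397 values. The median of its columns was 1 on both arrays, and 11933 and 11692 values were exactly 1 in the file, with no tolerance. Probe coordinates in the files are on mm9.

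Of 44397 spots, 43020 were gene spots for 39429 probes and 1377 were controls. Mean intensities were corrected with normexp (offset 50) and normalized by loess within each array (limma 3.58.1, R 4.3.3), with control spots and spots marked as outliers at weight 0. Spots of one probe were averaged without the 272 and 226 outlier spots of the arrays. Probes were kept if well above background in the cDKO channel on both arrays or in the control channel on both arrays, which left 29274 probes. Symbols came from the accession of the probe through a RefSeq table of GRCm38.p6 for 26412 probes, and from the file for 13017. None of that table's coordinates was used. A gene was represented by its brightest kept probe, which gave 23306 genes, of which 16335 had a symbol. Among 241 genes called and measured by several probes, 0 had a probe called in the opposite direction.

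Every log2 ratio was turned to labelled cDKO over control. The mean of both arrays was tested against 0 with limma (lmFit, eBayes, two-sided, Benjamini-Hochberg over the probes, threshold 0.05), with 1 residual degree of freedom and a prior of 13.9 degrees of freedom. Values are given as mean log2 ratio ± SD. A fixed rule without a test counted genes changed at least 2-fold on both arrays. Gene lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 28 lists. At that preset the p-values of lists measure the spread between genes, taken as nearly independent, and not variation between arrays. The lists were tested again with an estimated correlation and with fry. With 1 residual degree of freedom hardly any list can pass with an estimated correlation, so a loss there does not argue against a shift. The main tests, the lists and the other settings were mostly fixed before the data were examined. Genes named are Tbx2, Tbx3, Tbx18 and the sex genes, the 12 highest and the 12 lowest called genes with the same direction on both arrays, and up to 4 members of each list with the largest mean ratio and the same direction on both arrays. Symbols made of accessions or clone names were passed over, and some genes that the rule takes are not reported here.

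The fit was tested on simulated data for the comparison of labelled cDKO with control, in 6 sets of 29274 probes with 100 probes changed 2-fold and 100 changed 4-fold. It recovered 92 to 100 of the 2-fold probes and 100 of 100 of the 4-fold probes. False calls made up 11.1% to 22.4% of the calls, above the nominal 5%, and 0 unchanged probes reached 2-fold on both arrays. The noise was drawn independently for each array and probe from the fitted variance. These rates hold for that setting and need not hold for the data. A simulated shift of 1 log2 unit in the endothelium list gave an adjusted p of 6.22e-53, with 0 other lists called.

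The alternatives were the processed signals, normexp with offset 0, median centring, Aquantile after loess, other filters on dim probes, the deposited value table, the mean of a gene's probes, an intensity trend or robust eBayes, other fold thresholds, and each array alone. A threshold of 0.01, lists without chosen members, counts without liver, kidney tubule and sex genes, and 10000 random lists matched on intensity were added after the data had been seen. Plots were drawn with matplotlib.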

Results

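Gene expression in the ureter, the muscular tube that carries urine from kidney to bladder, was compared between embryos labelled cDKO and control embryos at stage E18.5. The genotype joins a Cre allele of Tbx18, a gene of the ureteric mesenchyme, with floxed alleles of Tbx2 and Tbx3, which encode T-box transcription factors. The comparison addressed which transcripts were deregulated in such ureters. There was 1 array of male RNA and 1 of female RNA, each with both genotypes, so that n = 2 ratios. Between 72.1% and 81.6% of the 43020 gene spots were well above background per channel, the median signal was 12.1 to 16.8 times the background, and 1 spot was saturated. The number of arrays limits the precision.

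Transcripts of the targeted genes were not lower in the RNA labelled cDKO. Tbx18 had a log2 ratio of 0.81 on both arrays (adjusted p = 0.00778). Tbx2 rose by 0.74 ± 0.42 (SD, n = 2; adjusted p = 0.0273), with 1.04 on the male array and 0.44 on the female array. Tbx3 rose by 0.66 ± 0.16 (SD, n = 2; adjusted p = 0.0305). Each gene was measured by 1 probe on mm9, at chromosome 9, 87599514 to 87599573 for Tbx18, chromosome 11, 85655391 to 85655450 for Tbx2, and chromosome 5, 120134511 to 120134570 for Tbx3. For Tbx2 and Tbx3 the labels do not say which exons the floxed alleles lose, and a probe outside the deleted part does not check the genotype. Tbx18 carries the Cre allele and is not floxed per the labels, so that limit does not cover it. No level of Tbx18 was predicted from the Cre allele, and the cause of its rise was not tested. Because these values neither bear out nor oppose the label, every direction below is that of the RNA labelled cDKO. The calls of all 3 genes were lost with the processed signals (adjusted p of 0.156 for Tbx18, 0.268 for Tbx2 and 0.255 for Tbx3) and under median centring, while the direction stayed. Tbx2 and Tbx3 also lost theirs with offset 0, and Tbx2 without a filter.

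Sex transcripts fitted the labels in 3 of the 4 RNAs. Xist, the RNA that silences an X chromosome, had processed signals of 1212 and 1146 in the labelled cDKO and control RNA of the female array at one probe, and was not well above background in males. The Y-linked genes Ddx3y and Eif2s3y had signals of 2851 and 5159 in the male cDKO RNA and of 4236 and 6739 in the male control RNA. In the female array they were not well above background in the control RNA, but stood at 359.6 and 491 in the RNA labelled cDKO. These are 12.6% and 9.52% of the male cDKO signals, though the former were read in green and the latter in red. Kdm5d and Uty, dimmer Y-linked genes, were not well above background in either female RNA.

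Against control, 1036 of 23306 genes were called changed in the RNA labelled cDKO, 510 higher and 526 lower (limma, adjusted p under 0.05), and 3732 genes had an unadjusted p under 0.05. In simulated data 11.1% to 22.4% of the calls were false, and 0 unchanged probes passed 2-fold on both arrays. The simulated noise was independent, and 200 probes were changed, so neither value gives the error rate of the genes counted here. At least 2-fold changes on both arrays were found for 96 genes higher and 170 lower, and 8 genes passed 2-fold in opposite directions. All 266 genes of the first kind were also called, which the pooled variance makes nearly certain, so it is no separate support. The male array alone had 278 genes at least 2-fold higher and 320 lower, and the female array alone had 299 and 273. Across genes, which are not independent replicates, the ratios of the arrays had a Pearson correlation of 0.487 and a Spearman correlation of 0.328. Without loess, under median centring, these were 0.165 and -0.00429, and 163 genes were called higher and 157 lower. The deposited value table gave 0 and 0 calls by limma, with 2422 genes at an unadjusted p under 0.05, and an intensity trend gave 935 higher and 658 lower. With the processed signals 134 were called higher and 210 lower, so that the higher share of the calls was 39.0% in place of 49.2%, and 58.7% under the intensity trend. Of 81 called named genes, 37 kept the call in all alternatives with a test except the deposited value table, where 0 did.

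**Figure D1:**
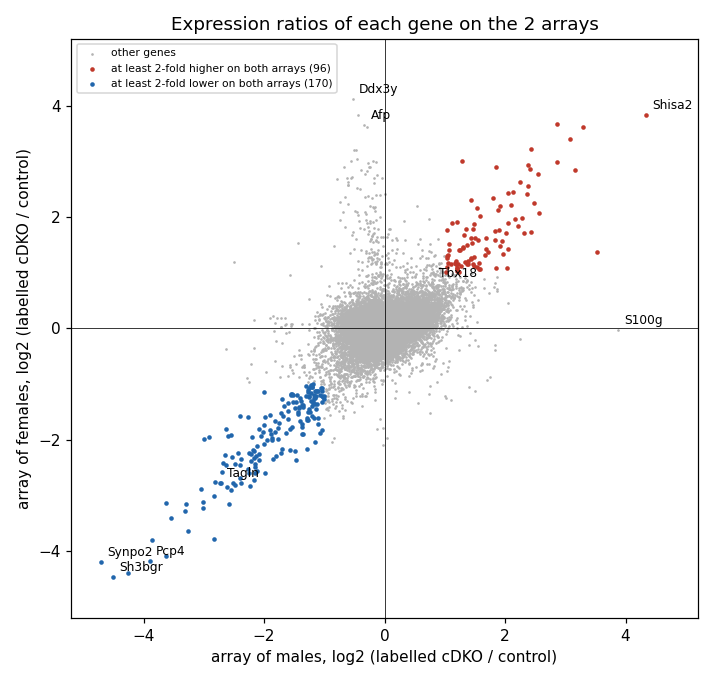
Log2 ratios of labelled cDKO over control RNA for each of 23306 genes on the array of males (x axis) and of females (y axis), with genes changed at least 2-fold on both arrays in colour. The 170 lower genes lie along the diagonal, while Ddx3y and Afp lie high on the female array alone and S100g high on the male array alone.

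Several of the lowest named genes are known from muscle. Sh3bgr fell by 4.48 log2 units, which is 22.4-fold lower (SD 0.036, n = 2; adjusted p = 5.35e-10). Synpo2, an actin-binding protein of muscle, was at -4.45 ± 0.37 (SD, n = 2), and Myh6, a cardiac myosin heavy chain, at -4.33 ± 0.094. Pcp4, a calmodulin regulator, was at -4.04 ± 0.20 and Myo18b, a muscle myosin, at -3.86 ± 0.32. Ckm, the muscle creatine kinase, was at -3.83 ± 0.040, Tnnt2, a troponin of the contractile apparatus, at -3.29 ± 0.017, and Myom1, a sarcomere protein, at -3.23 ± 0.10. The other lowest genes included Rims1, a presynaptic protein, at -3.48 and Bves, a membrane protein of muscle, at -3.45. With them were Mc4r, a melanocortin receptor, at -3.38, and Alx1, a homeobox factor, at -3.31. Order and size depend on the processing: in the deposited value table Synpo2 was at -4.56, Sh3bgr at -4.55 and Alx1 at -4.51. All 12 lowest genes were well above background in both RNAs of both arrays.

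The smooth muscle list fell as a whole. Of its 26 measured genes, 24 were lower and 0 higher, and 26 were lower when adjusted over the list alone. The median log2 ratio was -1.58, with -1.54 on the male array and -1.68 on the female array (camera adjusted p = 2.49e-54; adjusted p = 0.457 with an estimated correlation). Besides Synpo2 and Pcp4, the members with the largest changes were Ldb3, a Z-disc protein, at -2.97 ± 0.12 (SD, n = 2) and Tagln, the actin-associated transgelin, at -2.75 ± 0.037. No random list of 10000 matched on intensity had a median as low.

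Shisa2 was the highest named gene in the main setting. Its product restrains the maturation of WNT and FGF receptors, and its transcript was 16.9-fold higher in the RNA labelled cDKO (4.08 ± 0.36 log2, SD, n = 2; adjusted p = 1.61e-09). Its probe lies on chromosome 14, 60250369 to 60250428. Grm3, a glutamate receptor, rose by 3.27 ± 0.56, Scgb1c1, a secretoglobin, by 3.25 ± 0.23, Cox8b, a subunit of cytochrome c oxidase, by 2.93 ± 0.085, and Pou3f1, a POU domain transcription factor, by 3.16 on the male and 2.84 on the female array. In the deposited value table Grm3 stood at a log2 ratio of 4.51 and Shisa2 at 4.11, so their order depends on the processing. Dkk1, a secreted WNT inhibitor, and Pappa2, a protease of IGF binding proteins, rose by 2.66 ± 0.39 and 2.66 ± 0.16. Cyp2e1, a cytochrome P450, rose by 2.64 ± 0.32 and Atp8a2, a lipid flippase, by 2.47 ± 0.13. Mup9 at 3.46 and Mup20 at 2.44 belong to the major urinary protein family, whose near-identical members one probe can detect together, so their identity is uncertain. Cdh16, a cadherin of kidney epithelium, was at 3.52 on the male array and 1.37 on the female array, and lost its call with the processed signals and with robust eBayes.

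**Figure D2:**
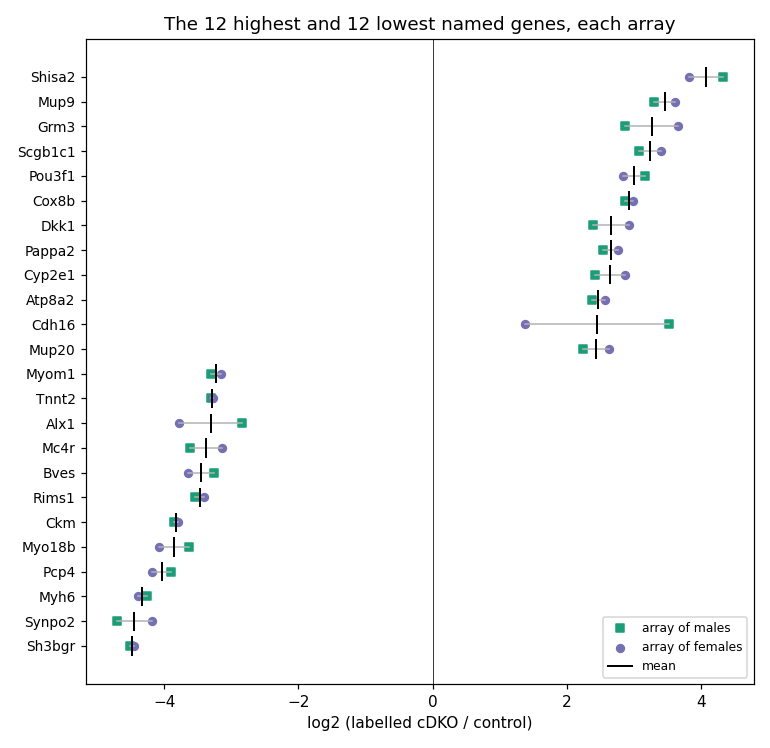
Log2 ratios of labelled cDKO over control RNA for the 12 highest and 12 lowest named genes, with squares for the array of males, circles for the array of females and a bar at the mean. In the main setting Shisa2 has the highest mean (4.08) and Sh3bgr the lowest (-4.48), and Cdh16 differs most between the arrays.

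WNT pathway genes shifted upwards, with a median of 0.58. Of 35 measured genes 16 were higher and 1, Nkd2, was lower, and 24 and 1 were so when adjusted over the list alone (camera adjusted p = 1.60e-20; adjusted p = 0.457 with an estimated correlation). The list of kidney markers was higher in the same RNA, with a median of 0.85 (0.82 on the male array and 0.44 on the female array; adjusted p = 0.457 with an estimated correlation). The WNT list holds receptors, ligands, targets and inhibitors. Besides Shisa2 and the inhibitor Dkk1, Shisa3, a relative of Shisa2, rose by 2.31 ± 0.35 (SD, n = 2) and Lgr5, a receptor for R-spondins and a WNT target, by 2.30 ± 0.22. Shisa2, Dkk2 and Bmper may have been picked by the study on these samples, so the direction of the WNT and BMP lists is not independent evidence. Without them the adjusted p was 1.47e-18 for the WNT list and 0.0133 for the BMP list. Nkd2 lost its call with the processed signals, under median centring, with offset 0 and without a filter.

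Extracellular matrix and fibroblast genes were higher as lists. In the fibroblast and adventitia list 9 of 22 genes were higher and 0 lower, with 14 higher when adjusted over the list alone, and the median was 0.53 (camera adjusted p = 3.16e-09; adjusted p = 0.457 with an estimated correlation). Col1a2 rose by 1.22 ± 0.33 (SD, n = 2), Fbln2, an elastic matrix protein, by 1.03 ± 0.21 and Lum, a proteoglycan, by 0.99 ± 0.39, while Col1a1 was at 1.87 on the male array and 0.67 on the female array. In the TGF-beta and matrix list 8 of 20 genes were higher and 0 lower, with 13 higher and 1 lower when adjusted over the list alone, and the median was 0.53 (camera adjusted p = 3.26e-07; adjusted p = 0.457 with an estimated correlation). Lox, an enzyme that crosslinks collagen, rose by 1.32 ± 0.13 and Fn1, fibronectin, by 1.11 ± 0.37. With the processed signals Fbln2, Lum, Col1a1 and Fn1 lost their calls, as did Fbln2, Lum and Fn1 under median centring and Col1a1 with robust eBayes.

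Genes of retinoic acid handling were also higher, with 3 of 15 called, 7 when adjusted over the list alone, and a median of 0.41 (camera adjusted p = 7.52e-05; adjusted p = 0.457 with an estimated correlation). The called members include Stra6, a retinol transporter, at 1.65 ± 0.45 (SD, n = 2), and Aldh1a3, an enzyme that makes retinoic acid, at 1.00 ± 0.38. Notch pathway genes had a median of 0.28 (0.45 on the male array and 0.16 on the female array), with 2 of 14 called, Heyl at 0.92 and Hey2 at 0.72, and 3 when adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.457 with an estimated correlation). BMP pathway genes had a median of 0.20 (0.39 on the male array and 0.12 on the female array), with 3 of 20 called and 7 when adjusted over the list alone (camera adjusted p = 0.00457; adjusted p = 0.457 with an estimated correlation). Smad6, an inhibitory SMAD, was at 0.80, Bmper, a BMP-binding protein, at 0.72 and the ligand Bmp4 at 0.68. Calls of Aldh1a3, Heyl, Hey2, Smad6, Bmper and Bmp4 were lost both with the processed signals and under median centring, and that of Bmp4 also with offset 0. The hedgehog list had a median of 0.32 (0.49 on the male array and 0.14 on the female array) with 0 of 12 genes called and 3 when adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.495 with an estimated correlation).

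The FGF list did not pass as a whole (median 0.096, with 0.19 on the male and 0.14 on the female array, camera adjusted p = 0.0963). Under median centring it passed, with a median of 0.30 (camera adjusted p = 0.0222). In the main setting 5 of its 16 genes were higher and 3 lower, the same counts as when adjusted over the list alone. Fgfr4, a receptor, rose by 1.49 ± 0.25 (SD, n = 2), Etv5, a transcription factor, by 1.12 ± 0.17 and Fgf9, a ligand, by 0.85 ± 0.44. Etv1 fell by 1.07. So did the ligands Fgf7 by 0.84 and Fgf10 by 0.72 (-1.02 on the male and -0.41 on the female array), both named after their values were seen. With the processed signals Etv5, Fgf9, Etv1, Fgf7 and Fgf10 lost their calls, and under median centring Fgf9, Etv1, Fgf7 and Fgf10 did, while Fgf10 also lost it with offset 0 and without a filter. Among 10 measured members of the T-box list, which leaves out Tbx2, Tbx3 and Tbx18, Tbx4 was called and rose by 1.65 ± 0.044. The median of that list was -0.032 (0.049 on the male array and -0.040 on the female array) while its mean was 0.14 (camera adjusted p = 0.606). Among mesenchymal transcription factors 2 of 21 were higher, Foxc2 at 1.05 and Nr2f2 at 0.71, and 6 when adjusted over the list alone (median 0.14, with 0.27 on the male and 0.32 on the female array; camera adjusted p = 0.00936; adjusted p = 0.457 with an estimated correlation). Both calls were lost with the processed signals, and that of Nr2f2 under median centring.

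Cell cycle genes differed little. The proliferation list had a median of 0.14 (0.18 on the male array and 0.24 on the female array) and 0 of 21 members called, also when adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.457 with an estimated correlation), with Cdc20 at 0.56 and Mcm2 at 0.52. The CDK inhibitor list had 0 of 7 called and a median of -0.028 (0.030 on the male array and -0.16 on the female array) against a mean of 0.0072 (camera adjusted p = 0.876), with Cdkn1c at 0.47 ± 0.44 (SD, n = 2).

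Lists of the urothelium, the epithelium that lines the ureter, did not pass. The superficial and intermediate list had 0 of 18 genes called and a median of 0.15 (0.22 on the male array and 0.063 on the female array; camera adjusted p = 0.0862), with Gata3 at 0.49 and Krt8 at 0.43. It passed with the processed signals (camera adjusted p = 0.0461), without a filter (0.0316) and in the deposited value table (0.0179). The basal and general epithelium list had a median of 0.12 (0.26 on the male array and -0.024 on the female array; camera adjusted p = 0.524), in which the keratins Krt17 and Krt14 were lower at -0.93 ± 0.56 and -0.71 ± 0.22 (SD, n = 2), and 3 genes were higher and 2 lower when adjusted over the list alone. Neither keratin kept its call with the processed signals or under median centring.

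Among markers of other cell types, the kidney list had the highest median, 0.85 (0.82 on the male array and 0.44 on the female array), with 8 of 14 genes higher, the same when adjusted over the list alone (camera adjusted p = 1.02e-08; adjusted p = 0.457 with an estimated correlation). The nephron genes Lhx1 and Six2 rose by 2.06 ± 0.13 (SD, n = 2) and 1.86 ± 0.22, and Pax8 was at 2.03 and 1.09 on the male and female array. The control RNA was well above background for Lhx1 on 1 of the 2 arrays, so its ratio on the other depends on the background offset. The endothelium list had 4 of 15 genes higher, 6 when adjusted over the list alone, and a median of 0.36 (camera adjusted p = 0.000311, and 0.457 with an estimated correlation). Among its called genes were Plvap at 0.97 and Cdh5 at 0.68 (0.94 on the male and 0.42 on the female array). The red blood cell list had a median of 0.38 (0.45 on the male array and 0.25 on the female array). Of its 13 genes 1 was called, Slc4a1 at 0.62, and 6 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00363, and 0.457 with an estimated correlation). Its list call was lost under median centring (camera adjusted p = 0.0995). In the cartilage list 4 of 14 collagens and other genes were higher, 5 when adjusted over the list alone (median 0.16, with 0.11 on the male and 0.22 on the female array; camera adjusted p = 0.0283; adjusted p = 0.457 with an estimated correlation), with Col9a2 at 0.88 and Col11a1 at 0.65. With the filter on both channels its median was -0.043 and its call was lost (camera adjusted p = 0.0533). Median centring (0.0773) and the deposited value table (0.201) lost the call too. The immediate early list had a median of 0.19 (0.51 on the male array and 0.030 on the female array) with 1 of 16 genes called, Klf4 at 1.14, also when adjusted over the list alone (camera adjusted p = 0.0073; adjusted p = 0.683 with an estimated correlation). Pax8, Plvap, Cdh5, Slc4a1, Col9a2, Col11a1 and Klf4 lost their calls with the processed signals, and Cdh5, Slc4a1, Col9a2 and Col11a1 also under median centring. Further losses were those of Cdh5 and Slc4a1 with offset 0, of Cdh5, Slc4a1 and Col11a1 without a filter, of Slc4a1 and Col11a1 with an intensity trend, and of Plvap with the mean of probes.

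Besides smooth muscle, 4 lists were called lower by camera. The skeletal muscle list had 5 of 14 genes lower, with 5 lower and 1 higher when adjusted over the list alone, and a median of -0.20, with -0.38 on the male and -0.17 on the female array (camera adjusted p = 7.52e-05; adjusted p = 0.457 with an estimated correlation). After Ckm, its lowest members were Acta1, an actin, at -2.65 ± 0.19 (SD, n = 2), and the troponins Tnnc2 at -1.87 ± 0.18 and Tnnt3 at -1.14 ± 0.094. The hypoxia list had a median of -0.27 with 1 of 14 genes called, Ankrd37 at -0.70, and 2 when adjusted over the list alone (camera adjusted p = 0.00281, and 0.457 with an estimated correlation). Under median centring its median was -0.091 and its call was lost (camera adjusted p = 0.105). The macrophage and leukocyte list had a median of -0.16 (-0.041 on the male array and -0.29 on the female array). Of its 18 genes 1 was called, H2-Aa at -1.02, also when adjusted over the list alone (camera adjusted p = 0.00543, and 0.457 with an estimated correlation). Its median was 0.00404 under median centring, where its call was lost (camera adjusted p = 0.149). The adipocyte list had 2 of 7 genes lower, also when adjusted over the list alone. These were Plin4 at -2.31 and Lpl at -0.74 (-1.15 on the male and -0.33 on the female array). The list median was -0.031, with -0.20 on the male and -0.15 on the female array (camera adjusted p = 0.0303, and 0.457 with an estimated correlation). With the processed signals the median was 0.029 and the call was lost (camera adjusted p = 0.15). The deposited value table lost it too (camera adjusted p = 0.234). Tnnt3, Ankrd37, H2-Aa and Lpl lost their calls with the processed signals and under median centring, and Lpl also with offset 0 and without a filter.

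The remaining lists did not pass. For neurons and glia the median was 0.14 (0.34 on the male array and 0.025 on the female array) with Ret at 0.86 and Fabp7 at 0.63 called (camera adjusted p = 0.0603), also when adjusted over the list alone. The gonad and adrenal list had a median of -0.057 (-0.019 on the male array and -0.021 on the female array) and a mean of 0.12 (camera adjusted p = 0.565), with Hsd3b1 called at 0.32 on the male array and 1.93 on the female array. The interferon list had a median of 0.036 (-0.067 on the male array and 0.075 on the female array) and a mean of -0.025 (camera adjusted p = 0.704), with Bst2 called at -0.73. All 4 of these calls were lost under median centring, those of Fabp7, Hsd3b1 and Bst2 also with the processed signals, those of Fabp7 and Hsd3b1 without a filter, that of Fabp7 with offset 0 and that of Hsd3b1 with robust eBayes. The mesothelium list had 0 of 6 genes called (camera adjusted p = 0.663). Of 28 lists 19 were called, 14 higher and 5 lower, 0 with an estimated correlation and 1 by fry, the hypoxia list (adjusted p = 0.0375). The estimated correlation could hardly call any list from 2 arrays. Even smooth muscle, with 26 of 26 genes lower when adjusted over the list alone, stood at a camera adjusted p of 0.457.

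**Figure D3:**
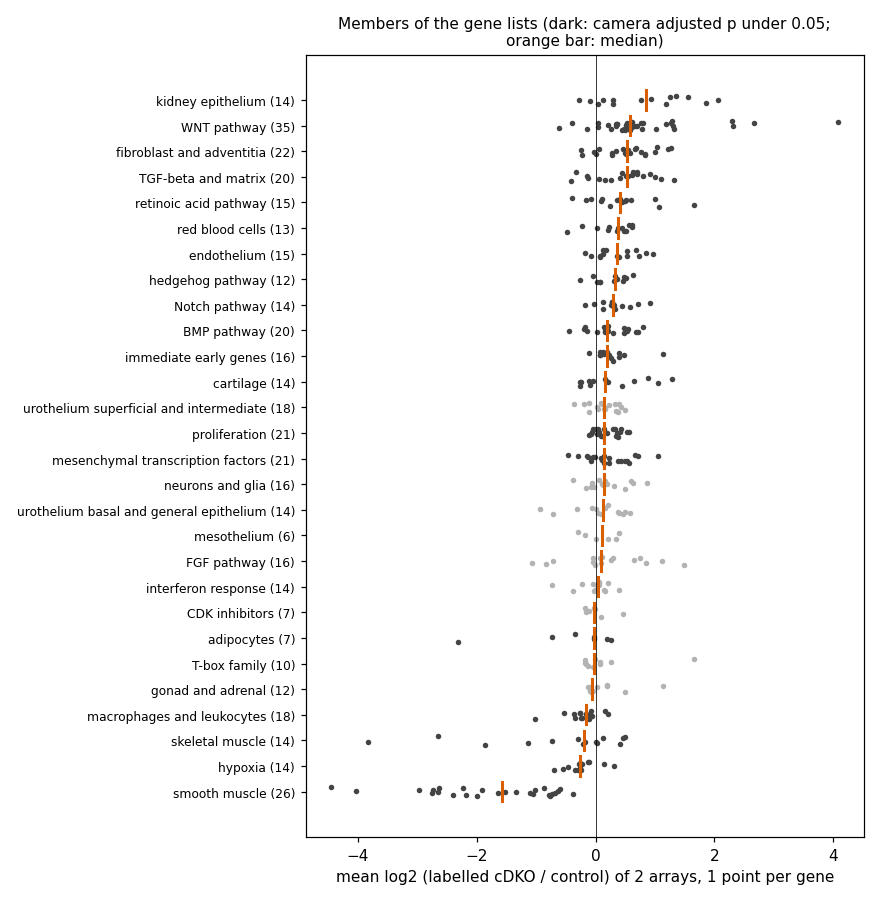
Mean log2 ratios of labelled cDKO over control RNA for each measured member of 28 gene lists, ordered by median (orange bar), with lists that camera called in dark grey and the number of genes in brackets. The smooth muscle list lies lowest, with a median of -1.58, and the kidney list highest, with 0.85.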

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

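The tests of male cells and of carry-over were chosen only after the result they measure was seen. The liver and kidney tubule lists were written after Afp, Fgg, S100g and Cdh16 had been seen and before the lists' medians were computed. With 1 array per sex, none of the differences between the sexes was tested, and sex runs together with dye orientation.

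On the female array the Y-linked genes Ddx3y and Eif2s3y had log2 ratios of labelled cDKO over control of 4.12 and 3.61, while both were below 0 on the male array (-0.53 and -0.29). The female control RNA was not well above background for either gene, so these ratios depend on the background offset. Against the higher of the gene's own control signal and the lowest control signal well above background, after loess and Aquantile, they were at least 8.86-fold and 10.6-fold higher, which 1 array leaves open to dye bias. Their processed signals in the female RNA labelled cDKO were 359.6 and 491, against 4.46 and 13.8 in the female control RNA. A list of 21 measured liver genes, written without Afp and Fgg, had a median log2 ratio of 2.36 on the female array and -0.31 on the male array, and 15 of the 21 were at least 2-fold higher on the former, among them Alb at 2.68 and Apoh at 3.20. The control RNA was not well above background for 1 of the 21, Apob, and with it at its bound the median was 2.34. A list of kidney tubule genes, written without S100g and Cdh16, had a median of 0.76 over 12 genes on the male array and 0.092 over 15 on the female array, where the 12 genes measured on both had -0.027. Of those 12 genes, 5 on the male and 0 on the female array were at least 2-fold higher, and 0 and 1 at least 2-fold lower.

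Carry-over from the male array on the same slide was argued against, since 0 Y-linked probes were well above background in the control channel of the female array. RNA from liver in the female cDKO sample may have given the liver transcripts, given the list's median of 2.36, which a value under 0.5 would have opposed. RNA of male cells in that sample may account for Ddx3y and Eif2s3y, whose shares of the male level differed 1.32-fold. However, only 2 of 5 Y-linked probes were bright enough to be used, and the shares set green signals against red ones. RNA from kidney in the male cDKO sample cannot be told apart from a change in the ureter, because the median of 0.76 lies between the bounds of 0.5 and 1 set beforehand. The kidney tubule list shares genes, among them Lrp2 and Cubn, with the kidney list, so it is not a separate set. Six2 (2.02 and 1.71) and Pax8 (2.03 and 1.09) were higher on both the male and the female array, and an effect of the genotype was not tested.

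Medians of 5 lists had opposite signs on the male and the female array, untested. The female minus male difference was -0.29 for the basal urothelium and general epithelium list, -0.19 for CDK inhibitors, -0.088 for the T-box family, -0.87 for mesothelium and 0.14 for the interferon response. There were 8 genes changed at least 2-fold in opposite directions, for example C3 at -1.44 on the male and 1.53 on the female array, and Npy at 1.39 and -1.05, both named after their values were seen.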

How the results depend on the processing

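The threshold of 0.01, the counts without liver, kidney tubule and sex genes, and the lists without chosen members were added after the data had been seen. No called named gene changed sign in any alternative that used both arrays, and on single arrays the rule that named most of them fixed the sign. Of 81 called, 37 kept the call, where measured, in all alternatives with a test except the deposited value table, where 0 did. No paired analysis was possible because each ratio already sets both RNAs of an array against each other and there is 1 group of ratios. Signal over background was 12.1 to 16.8, and 2 arrays limit all tests. Aquantile changes intensities and not ratios, and left 510 and 526 calls.

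With the processed signals 134 genes were called higher and 210 lower (113 and 198 of them shared with the main calls), 195 and 278 were 2-fold higher and lower on both arrays, 27 were opposite, and the correlations were 0.437 (Pearson) and 0.304 (Spearman). Under median centring 163 and 157 were called, 62 were opposite, and the correlations were 0.165 and -0.00429. The deposited value table gave 0 and 0 calls by limma, with 2422 genes at an unadjusted p under 0.05 and a prior of 2.13 degrees of freedom; 259 of its probes had exactly equal values on both arrays, with no tolerance. It gave 150 genes 2-fold higher, 24 opposite, and correlations of 0.459 and 0.308. Pearson was 0.458 with offset 0, 0.452 without a filter and 0.513 with the filter on both channels, and Spearman was 0.243 without a filter and 0.34 with the latter. An intensity trend called 935 genes higher and 658 lower, a higher share of 58.7%. At 1.5-fold 348 genes were higher, 401 lower and 53 opposite, and at 3-fold 34, 83 and 0. At an adjusted p under 0.01, 263 were called higher and 324 lower. Single arrays gave 278 to 299 genes 2-fold higher and 273 to 320 lower. Without the members of the liver, kidney tubule and sex lists 505 and 526 remained. Other kidney genes, such as Cdh16, Six2, Lhx1 and Pax8, stayed in, so the count does not measure RNA from other tissues.

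Tbx18, Tbx2 and Tbx3 lost their calls at log2 ratios of 0.77, 0.71 and 0.65 with the processed signals and with the deposited table, and of 1.01, 0.93 and 0.78 under median centring. Tbx2 also lost it at 0.74 with offset 0 and at 0.74 without a filter, and Tbx3 at 0.66 with offset 0. Adjusted p over the alternatives with a test reached 0.33 for Tbx18, 0.462 for Tbx2 and 0.589 for Tbx3.

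Adjusted p of lists crossed the threshold as follows. The superficial urothelium list passed at 0.0461 with the processed signals, 0.0316 without a filter and 0.0179 in the deposited table, the FGF list at 0.0222 under median centring, and the neurons and glia list at 0.034 with the mean of probes. The cartilage list missed it at 0.0773 under median centring, 0.0533 with the filter on both channels (where its median turned to -0.043) and 0.201 in the deposited table. The adipocyte list missed it at 0.15 with the processed signals (median turned to 0.029) and 0.234 in the deposited table. Under median centring macrophages were at 0.149 (median turned to 0.00404), red blood cells at 0.0995 and hypoxia at 0.105. With an estimated correlation 17 of the 19 calls were lost at 0.457, hedgehog at 0.495 and immediate early genes at 0.683. With fry smooth muscle and adipocytes stood at 0.203, BMP at 0.278, proliferation at 0.276, hedgehog and kidney at 0.35, immediate early genes at 0.606, and fibroblast, retinoic acid, WNT, Notch, TGF-beta, mesenchymal factors, cartilage, endothelium, macrophages, red blood cells and skeletal muscle at 0.256. Without Ckm and Acta1, which were removed because they had fallen, the skeletal muscle list stood at 0.0495. The cause was not tested.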

Other observations

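The dye tests and the exchange test, the list of cardiac and striated contractile genes and the count of neighbours were chosen only after the data had been seen. Contractile genes known from heart and striated muscle did not all move alike. Besides Myh6 and Tnnt2, Myl4 was at -2.83 on the male and -3.02 on the female array, and Actc1 at -2.63 and -2.46. Myl2, a ventricular myosin light chain, was at 0.54 and 0.61, and Nkx2-5, a cardiac transcription factor, at 0.083 and -0.049. Both were dim, with log2 intensities on the male array of 9.06 for Myl2 and 7.79 for Nkx2-5 against 16.5 for Actc1, so their ratios say little. The same limit holds for Tnnc1, with an intensity of 9.11, which was at -1.11 on the male and -1.61 on the female array. Tnni3, brighter at 10.8, was at -0.30 and -0.44. Of the 16 genes measured on both arrays, 5 on the male and 6 on the female array were at least 2-fold lower and 0 were 2-fold higher, with medians of -0.31 and -0.69. Each array measured 17 genes, the last one differing, with medians of -0.30 and -0.51.

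Among 16300 genes with a position, 7 pairs of genes within 100000 bases were both at least 2-fold higher or both 2-fold lower on both arrays, leaving out pairs whose symbols start with the same letters. Random assignment of the same directions gave a median of 2 pairs and at most 11 in 10000 draws (permutation p = 0.0264, one-sided). Counting linked genes as 1 group gave 6 groups (permutation p = 0.0485). Both values rest on Popdc3 and Bves, which belong to 1 gene family: without that pair there were 6 pairs (permutation p = 0.0625) or 5 groups (permutation p = 0.124). The pairs include Shisa2 and Atp8a2, 16247 bases apart on chromosome 14, and Cyp2e1, Scgb1c1 and Cox8b on chromosome 7. Tbx4, at 1.65, was measured 74119 bases from Tbx2.

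Tbx2, Tbx3 and Tbx18 were higher in the RNA labelled cDKO on both arrays. A dye effect was argued against, since the smallest of the 3 mean ratios over its standard error was 4.03 with the dyes exchanged between arrays. A larger share of non-muscle mesenchyme may account for the values: the mean of the 3 genes, 0.74, lay within the quartiles of the fibroblast and adventitia list (0.28 to 0.81). Setting a mean of 3 genes against the spread of single genes is a weak test. Samples exchanged on both arrays cannot be told apart from correct labels, because 0 probes named Cre were on the array. An effect of the genotype on Tbx18, or on transcripts of Tbx2 and Tbx3 outside the deleted part, also stays open and was not tested.

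Smooth muscle genes were lower and other lists higher in the RNA labelled cDKO. A dye effect was argued against, because the higher of the smooth muscle medians of the arrays was -1.54. A lower share of smooth muscle alone would raise every other cell type alike. The 6 lists of other cell types (103 genes) had medians from -0.16 to 0.53. A permutation of genes between lists gave p = 1e-05 (Kruskal-Wallis statistic, the smallest that 100000 permutations can give). These values argue against an equal shift of the measured ratios, although genes of one list are not independent. The lists also differ in intensity, and the offset narrows the ratios of dim genes most, so the share itself was not decided. A rise of fibroblast-like cells together with a loss of smooth muscle, and a change of expression within cells by genotype, both stay open and were not tested.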
